A study of Rattus norvegicus with 6 samples.

How the data were processed

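RNA was measured in the hearts of male Sprague–Dawley rats, an outbred laboratory strain, aged 8 weeks and weighing 250 to 300 g. Per the labels, 3 rats received saline and 3 received ISO at 1.5 mg/kg/day under the skin for 7 days. ISO is the labels' abbreviation and is read here as isoproterenol, an agonist of beta-adrenergic receptors. Each library came from a separate rat, per the series description, and each library was placed in its group by its own label. The series also concerns phosphoproteomic data, which were not analysed here.

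Per the series description, the authors sequenced 150 bp paired reads, aligned them to the rat genome with HISAT2 and counted them per gene with featureCounts. The deposited values are whole-number read counts per gene, not normalised, with 1 column per library. Versions of the aligner and the counter are not given in the sources used here. The submitters' processing notes list the mouse build mm10, whereas all 32883 rows with a gene name carry rat Ensembl identifiers. No genome coordinates were used here, so no gene is placed on a chromosome and bias from GC content or gene length was not examined. The library kit is named in the labels, but whether the counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

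The table held 33889 rows. Of these, 1006 carried only a numbered placeholder in place of a gene name, and these rows took 0.98% to 1.32% of the counts of a library. They were left out of library sizes and tests. A spreadsheet had turned 10 gene symbols into dates, and these were not renamed. Where rows shared a symbol, the row with the most counts kept it and stood for it in the gene lists, which affected 3946 rows, 119 of them outside RNA families. Counts of near-identical genes, such as those of the major histocompatibility complex, haemoglobins and ribosomal proteins, are uncertain because reads can be split between copies. Every pair of libraries differed by more than sampling noise, so none was counted as a duplicate.

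Differences were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test on the deposited counts, with trimmed mean of M values (TMM) scaling and edgeR's default filter on low counts, which left 13766 genes. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are log2 of ISO over saline. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM, the usual library-size scaled read count, follow TMM scaling unless unscaled CPM are named, and are given as mean ± SD over 3 libraries. Log2 CPM for principal components and list tests used a prior count of 2. The counting floor of 3 reads lay between 0.176 and 0.204 CPM per library.

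Before the data were examined, 38 gene lists with 865 entries were fixed, and 838 entries were found in the table. They comprised 18 lists of pathways, 4 lists that follow sample handling and RNA, and 16 lists of cell type markers. Lists with at least 3 tested members were tested with camera from limma 3.58.1, with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Adjustment ran within each kind of list. Camera compares a list with other genes, whereas fry tests whether a list's own genes move on balance one way.

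The genes named in the text were also chosen by a rule fixed before the data were examined. The rule took 12 fixed genes, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM, a proper symbol and no overlap between groups. From each pathway list it took up to 3 called members with the smallest p, or otherwise the 2 most abundant. From every other list it took up to 2 called members, or otherwise the most abundant. It gave 86 genes, of which 1 is not reported here. Any gene outside the rule is marked as chosen after its values were seen.

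The tests were tested on counts simulated for ISO against saline, with 50 genes changed at each of 4 fold sizes and 13622 genes passing the filter. edgeR recovered 10% of the genes changed 1.5-fold, 62% at 2-fold, 96% at 4-fold and 98% at 8-fold, and 15 of its 148 calls were false. DESeq2 recovered 22%, 74%, 100% and 100%, with 29 false among 177 calls. The voom method of limma recovered 10%, 60%, 96% and 98%, with 13 false among 145 calls. The share of false calls in the simulation was above the nominal 5% for all 3 tools.

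Alternatives fixed in advance were DESeq2's size factors, no scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, voom, an adjusted p under 0.01, the series' own rule, mitochondrial genes left out, the replicate number as a block, and each library left out in turn. The series' rule is an absolute log2 fold change over 0.5 with an unadjusted p under 0.05. Keeping the rows without a gene name was added after the data were seen.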

Results

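The data comprised 6 heart RNA-seq libraries, 3 from saline-treated rats and 3 from rats given ISO for 7 days. The series addresses myocardial hypertrophy and fibrosis, and its single comparison is ISO against saline. Saline libraries 1 to 3 held 14880391, 17299589 and 16776064 counts, and ISO libraries 1 to 3 held 15259502, 16454903 and 16175049 counts. Mitochondrially encoded genes took 25.3 ± 4.03% of the named counts in saline and 22.8 ± 0.153% in ISO (SD, n = 3 each).

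The first principal component held 40.7% of the variance of log2 CPM and separated the groups. ISO replicate 3 lay farthest from saline on it, at 49.1, and ISO replicate 2 lay nearest, at 7.56, while the saline libraries lay between −31.2 and −25.9. Spearman correlations across genes were 0.980 to 0.986 within saline, 0.968 to 0.980 within ISO and 0.957 to 0.978 between groups. Genes are not independent replicates, and no test was run on these values.

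**Figure D1:**
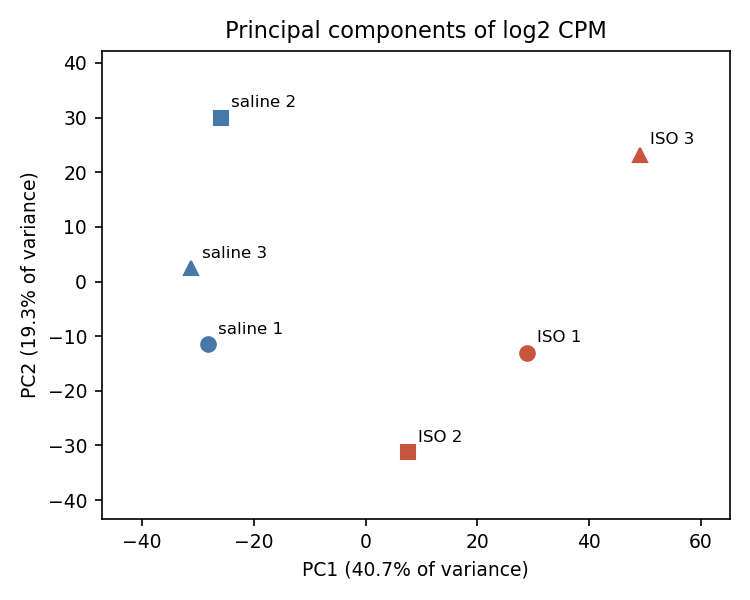
Scores of the 6 libraries on the first and second principal components of log2 CPM, with 1 point per library. The first component (40.7% of variance) separates ISO (red) from saline (blue), and ISO replicate 3 lies farthest out at 49.1.

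ISO hearts differed from saline hearts in 409 of 13766 tested genes, with 203 higher and 206 lower. Changes of more than 1 on the log2 scale made up 108 of the rises and 56 of the falls. The largest rises taken by the naming rule included Postn, which encodes the matrix protein periostin (ENSRNOG00000012660), at 5.71 (SE 0.88, edgeR adjusted p = 0.02). They also included Thbs4, a thrombospondin (ENSRNOG00000012471), at 5.51 (SE 0.59, edgeR adjusted p = 0.0115). Postn stood at 868 ± 1003 CPM in ISO and 16.5 ± 5.87 CPM in saline, and Thbs4 at 168 ± 89.7 against 3.71 ± 2.49 CPM. The other large rises were Cthrc1 at 4.99, C1qtnf3 at 4.48, Angptl4, an inhibitor of lipoprotein lipase, at 4.16, Ccn5 at 3.76, Gpnmb at 3.75, Nppa at 3.40, the hexokinase gene Hk3 at 3.09 and Ltbp2, a latent TGF-beta binding protein, at 3.08. Their adjusted p by edgeR ranged from 0.017 for Angptl4 to 0.045 for C1qtnf3. Several of these values rest on ISO replicate 3 for their size. In ISO replicates 1 to 3, Cthrc1 stood at 9.77, 6.92 and 71.8 CPM, C1qtnf3 at 4.26, 1.43 and 16.3 CPM and Gpnmb at 78.6, 62.7 and 368 CPM. Without ISO replicate 3 their log2 fold changes were 3.17, 3.12 and 2.49 and all were still called, whereas Hk3 at 2.38 was not (edgeR adjusted p = 0.0528). Ltbp2 stood at 2.33 in that fit. Saline libraries also moved values, with Angptl4 at 5.44 without saline replicate 3 and Ccn5 at 4.58 without saline replicate 1.

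Among genes taken by the naming rule, the 10 largest falls were smaller than the 10 largest rises. Dcdc5 changed by −2.92 (SE 0.54, edgeR adjusted p = 0.0327) and Hemgn, an erythroid gene, by −2.57 (SE 0.47). Htr2a, the serotonin 2A receptor, changed by −2.54 (SE 0.48), and these genes all stood under 5 CPM in saline. The others were Crybb1 at −2.25, the transcription factor Mycn at −1.93, Sec14l5 at −1.89, the lipid hydrolase Pnpla3 at −1.89, the histocompatibility gene RT1-CE10 at −1.73 and the IgE receptor Fcer2 at −1.57. Fbxl22, a cardiac F-box protein gene (ENSRNOG00000017684), stood at 46.2 ± 4.24 CPM in ISO against 137 ± 9.63 CPM, a change of −1.56 (SE 0.11, edgeR adjusted p = 0.00262). RT1-CE10 belongs to a family of near-identical genes, so its counts are uncertain. LOC103690108, outside the rule and named after its values were seen, fell further than these genes. It stood at 35.7, 28.5 and 39.3 CPM in saline replicates 1 to 3 and at 0.188, 0.187 and 0 CPM in ISO replicates 1 to 3.

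The number of calls depended on single libraries. Without saline replicate 1, 2 or 3, 14, 6 and 7 genes were called higher and 12, 16 and 5 lower. Without ISO replicate 1 the counts were 9 and 14, without ISO replicate 2 they were 492 and 346, and without ISO replicate 3 they were 171 and 124. Of the 59 named genes that were called, 6, 5 and 4 kept their call without saline replicate 1, 2 or 3, and 7, 58 and 47 without ISO replicate 1, 2 or 3. Fbxl22 kept its call in all 6 of these fits, and none of the 59 reversed. Groups did not overlap in 28.8% of tested genes, where chance gives 10%. TMM scaling gave 203 higher and 206 lower genes with a median log2 fold change over all genes of 0.02. Without scaling the split was 280 higher and 123 lower and the median moved to 0.13.

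Among genes known to rise in the hypertrophied heart, Nppa, the gene of atrial natriuretic peptide (ENSRNOG00000008176), was 10.6-fold higher in ISO. It stood at 1170.3 ± 295 CPM against 111 ± 93.2 CPM (SD, n = 3), a log2 fold change of 3.40 (SE 0.56, edgeR adjusted p = 0.0244). Nppb, the gene of B-type natriuretic peptide, was not called, at 67.6 ± 29.7 against 113 ± 15.6 CPM and −0.74 (SE 0.29, edgeR adjusted p = 0.186). Rcan1, an inhibitor of calcineurin, fell by 1.34 on the log2 scale (edgeR adjusted p = 0.0142), and Enah, which promotes actin filament growth, fell by 0.57 (edgeR adjusted p = 0.0204). The transcription factor gene Mef2a, named after its values were seen, was also lower at −0.57. Of 24 tested members of this list, 1 was higher, 3 were lower and 20 were not called, with 4 higher and 3 lower adjusted over the list alone. The list's median was 0.14 (camera adjusted p = 0.976), and fry gave the opposite direction to camera. Called members numbered 0, 1 and 0 without saline replicate 1, 2 or 3, and 1, 8 and 4 without ISO replicate 1, 2 or 3.

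Nppa rose in an ISO group whose replicate 1 held RNA of atrial genes. The atrial myosin light chain gene Myl7, named after its values were seen, had 9, 25 and 17 counts in saline and 1128, 17 and 0 in ISO replicates 1 to 3. Nppa stood at 1125, 1486 and 901 CPM in those libraries, and at 42.8, 217 and 72.2 CPM in saline. Its call was lost without saline replicate 1 (edgeR adjusted p = 0.068), saline replicate 3 (0.121) or ISO replicate 1 (0.0749). The log2 fold change was then 3.01 (SE 0.50), 3.17 (SE 0.67) and 3.42 (SE 0.63), against 3.40 (SE 0.56) with all libraries, so leaving out ISO replicate 1 did not shrink the change. Without saline replicate 2, the saline library with the most Nppa, it was 4.34 (SE 0.35, edgeR adjusted p = 0.0184). The atrial marker list had 10 tested members with none called and a median of 0.21 (camera adjusted p = 0.619), while 4 members had an unadjusted edgeR p under 0.05, DESeq2 called 1 and voom 0. The filter left out Sln, Bmp10 and Mybphl, named after their values were seen, with 670, 192 and 157 counts in ISO replicate 1. This list test was therefore not suited to show atrial RNA in a single library.

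The myosin and actin genes of the fetal and adult heart were mostly not called. Myh7, the beta myosin heavy chain, stood at 4596 ± 1915 CPM in ISO and 2287 ± 133 in saline, with every ISO library above every saline library, yet its change of 1.01 had an edgeR adjusted p of 0.0791. Myh6, the alpha myosin heavy chain, gave −0.57 (SE 0.23, edgeR adjusted p = 0.195), and the skeletal actin gene Acta1 gave 0.22 (SE 0.27, edgeR adjusted p = 0.674). Ankrd1, a stretch-responsive muscle gene, gave −0.06 (SE 0.18, edgeR adjusted p = 0.886), and without scaling its sign changed. Actc1, the cardiac actin gene, fell from 15452 ± 651 to 6809.9 ± 602 CPM, a change of −1.18 (SE 0.16, edgeR adjusted p = 0.0161). It was the only called gene among 18 cardiomyocyte markers, which had a median of −0.22 (camera adjusted p = 0.00988; adjusted p = 0.872 with an estimated correlation).

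**Figure D2:**
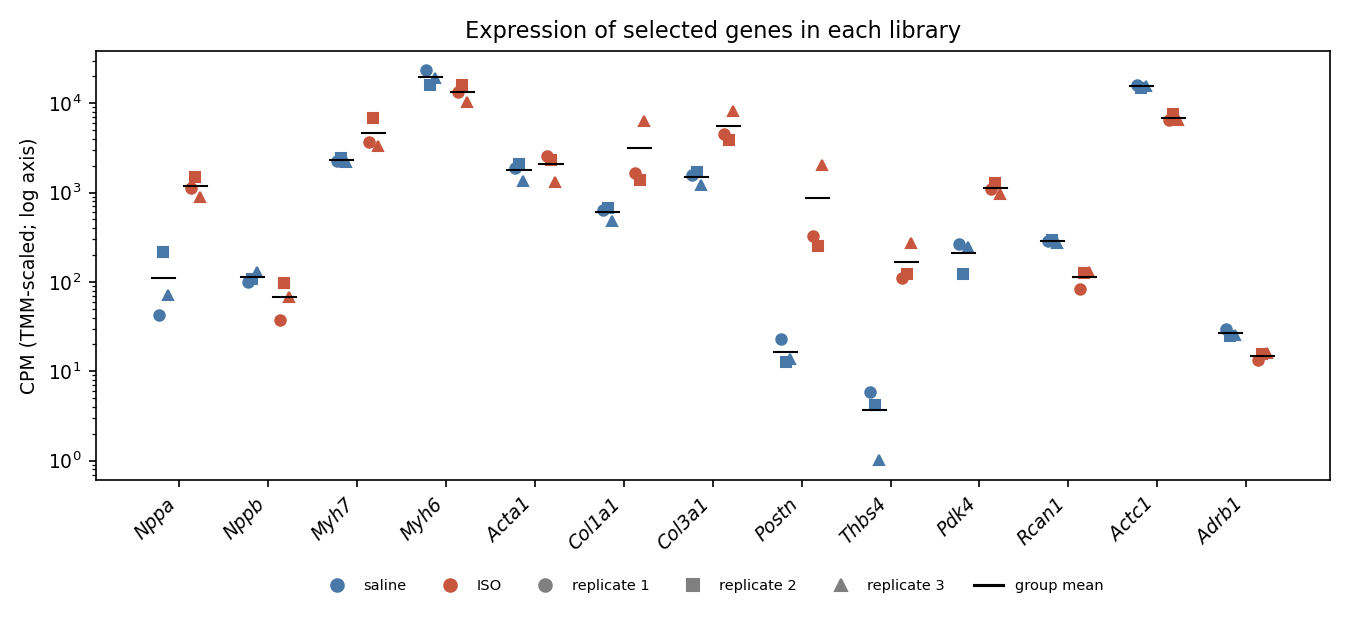
CPM of 13 genes in each of the 6 libraries on a log axis, with bars at the group means and 1 symbol per replicate number. Nppa, Myh7, Col1a1, Col3a1, Postn, Thbs4 and Pdk4 are higher in every ISO library than in any saline library. Nppb, Rcan1, Actc1 and Adrb1 are lower in every ISO library. Of these genes, Myh7, Col1a1 and Nppb were not called.

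Of 41 tested collagens and structural matrix genes, 14 were called higher in ISO, none lower and 27 were not called (31 higher and 1 lower adjusted over the list alone). Col3a1, a fibrillar collagen (ENSRNOG00000003357), stood at 5508 ± 2315 CPM in ISO and 1498 ± 245 CPM in saline, a change of 1.88 (SE 0.29, edgeR adjusted p = 0.0204). Fbln1, the gene of fibulin 1, changed by 1.05 (SE 0.12, edgeR adjusted p = 0.0138) and Col18a1 by 1.03 (SE 0.12, edgeR adjusted p = 0.0138). Col1a1, the main fibrillar collagen, was at 3131 ± 2796 against 599.8 ± 102 CPM and was not called at 2.38 (SE 0.55, edgeR adjusted p = 0.0584). Ccn2, a matricellular growth factor gene, gave 0.46 (SE 0.41, edgeR adjusted p = 0.55). The list's median was 1.14 (camera adjusted p = 3.14e-15; adjusted p = 0.439 with an estimated correlation; fry adjusted p = 0.0756). ISO replicate 3 stood apart, with a list median of 1.80 relative to saline against 1.08 and 0.52 in ISO replicates 1 and 2.

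Single libraries also moved the matrix values. Without ISO replicate 3, Postn stood at 4.13 and was still called (edgeR adjusted p = 0.00109), and Col1a1 at 1.34 was then called (edgeR adjusted p = 0.0146). Called members of the matrix list numbered 1, 0 and 1 without saline replicate 1, 2 or 3, and 2, 30 and 18 without ISO replicate 1, 2 or 3. The median of the matrix list moved less, at 1.23, 1.14 and 1.16 and at 1.16, 1.48 and 0.798 in the same fits. Collagen processing and matrix turnover genes had 4 of 28 members higher and none lower (20 higher and 1 lower adjusted over the list alone), among them the gelatinase gene Mmp2 at 1.03 (SE 0.14, edgeR adjusted p = 0.0157), the protease gene Ctsk at 1.23 and the procollagen protease gene Bmp1 at 0.81. Their median was 0.80 (camera adjusted p = 2.34e-08; adjusted p = 0.439 with an estimated correlation).

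Activated fibroblast and myofibroblast genes had 5 of 19 members higher and 1 lower (9 higher and 1 lower adjusted over the list alone). Itgbl1 changed by 1.10 (SE 0.15, edgeR adjusted p = 0.0157), Prss23 by 0.80 (SE 0.12) and Aebp1 by 1.00 (SE 0.15), and the lower member was the tendon transcription factor gene Scx at −1.01, named after its values were seen. The list's median was 0.80 (camera adjusted p = 1.38e-05; adjusted p = 0.439 with an estimated correlation). In the TGF-beta pathway, 2 of 30 members were higher and none lower (10 higher and 0 lower adjusted over the list alone), namely the ligand gene Tgfb3 at 1.19 (SE 0.21, edgeR adjusted p = 0.0281) and Ltbp3, a latent TGF-beta binding protein gene, at 0.91 (SE 0.16, edgeR adjusted p = 0.0289). This list had a median of 0.36 (camera adjusted p = 9.57e-04; adjusted p = 0.439 with an estimated correlation).

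Resting fibroblast markers had 3 of 18 members higher and 1 lower (10 higher and 1 lower adjusted over the list alone), with Scara5 at 0.82 (SE 0.09, edgeR adjusted p = 0.0137) and Dpt at 0.87 (SE 0.13, edgeR adjusted p = 0.019). Their median was 0.41 (camera adjusted p = 0.00168; adjusted p = 0.255 with an estimated correlation; fry adjusted p = 0.0221).

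Of 23 macrophage and monocyte markers, 8 were called higher in ISO, none lower and 15 were not called (19 higher and 0 lower adjusted over the list alone). The complement genes C1qa and C1qc, which tissue macrophages express, changed by 1.15 (SE 0.14, edgeR adjusted p = 0.0138) and 0.91 (SE 0.11, edgeR adjusted p = 0.0138). The median of the list was 1.01 (camera adjusted p = 3.45e-13; adjusted p = 0.351 with an estimated correlation; fry adjusted p = 0.0755), and it was 1.61 in ISO replicate 3 against 0.93 and 0.72 in ISO replicates 1 and 2. Complement genes, which share C1qa, C1qb and C1qc with the macrophage markers, had 6 of 19 members higher and none lower (14 higher and 0 lower adjusted over the list alone), including the protease gene C1s at 0.67 (SE 0.12, edgeR adjusted p = 0.0312). Their median was 0.81 (camera adjusted p = 2.08e-08; adjusted p = 0.439 with an estimated correlation).

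Other immune lists held few calls. Cytokine and chemokine genes had 1 of 20 members lower and none higher (1 higher and 1 lower adjusted over the list alone), namely the chemokine gene Cxcl12, which changed by −0.97 (SE 0.12, edgeR adjusted p = 0.0138). The median of that list was −0.05 and its mean 0.05 (camera adjusted p = 0.976), and the median was above 0 without scaling. Interferon-response and antigen presentation genes had none of 31 members called by edgeR (2 higher and 1 lower adjusted over the list alone), a median of 0.27 and a camera adjusted p of 0.0825, with B2m at −0.16 (SE 0.18) and Cd74 at 0.30 (SE 0.15). At an unadjusted p under 0.05 edgeR gave 5 of them, and DESeq2 called 3 and voom 0.

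Calcium handling and ion channel genes had 1 of 25 members higher and 2 lower (1 higher and 7 lower adjusted over the list alone). Jph2, which holds the junction between the cell membrane and the calcium store, changed by −1.26 (SE 0.20, edgeR adjusted p = 0.0204), the sodium-calcium exchanger gene Slc8a1 by −0.61 (SE 0.10, edgeR adjusted p = 0.0255) and the potassium channel gene Kcnj5 by 0.72 (SE 0.12, edgeR adjusted p = 0.0276). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at 7521 ± 1076 CPM in ISO and 12310.0 ± 289 CPM in saline and was not called at −0.71 (SE 0.17, edgeR adjusted p = 0.0655). The list's median was −0.40 (camera adjusted p = 5.64e-04; adjusted p = 0.607 with an estimated correlation). Adrb1, the beta-1 adrenergic receptor gene (ENSRNOG00000017002), fell from 26.8 ± 2.72 to 14.9 ± 1.46 CPM, a change of −0.85 (SE 0.13, edgeR adjusted p = 0.0205). It was the only called gene among 39 beta-adrenergic signalling genes (0 higher and 1 lower adjusted over the list alone), whose median was −0.05 (camera adjusted p = 0.361) and was above 0 without scaling.

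Genes of fatty acid uptake and oxidation moved both ways, with 3 of 34 members higher and 2 lower (6 higher and 8 lower adjusted over the list alone). Pdk4, an inhibitory kinase of pyruvate dehydrogenase (ENSRNOG00000009565), was 5.25-fold higher at 2.39 (SE 0.29, edgeR adjusted p = 0.0138). Ppara, a nuclear receptor that drives fatty acid oxidation genes, was lower at −0.85 (SE 0.16, edgeR adjusted p = 0.033). The list's median was −0.09, its mean 0.13 and its camera adjusted p 0.545, and the median was 0.00 without scaling.

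Glucose uptake and glycolysis genes had 1 of 26 members higher and 3 lower (3 higher and 4 lower adjusted over the list alone), with the muscle enolase gene Eno3 at 1.25 (SE 0.21, edgeR adjusted p = 0.0244), the regulatory enzyme gene Pfkfb2 at −1.19 (SE 0.15, edgeR adjusted p = 0.0138) and the monocarboxylate transporter gene Slc16a1 at −0.63 (SE 0.12, edgeR adjusted p = 0.0346). Their median was −0.11 (camera adjusted p = 0.215). Nuclear genes of the respiratory chain had none of 38 members called by edgeR (0 higher and 4 lower adjusted over the list alone), with the ATP synthase genes Atp5f1b at −0.13 (SE 0.19) and Atp5f1a at −0.21 (SE 0.16). An unadjusted edgeR p under 0.05 was reached by 9, and DESeq2 called 7 and voom 0. Their median was −0.20 (camera adjusted p = 2.67e-06; adjusted p = 0.703 with an estimated correlation).

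Among cell division genes, the D-type cyclins Ccnd2 at −1.14 (SE 0.17, edgeR adjusted p = 0.0178) and Ccnd1 at −0.93 (SE 0.16, edgeR adjusted p = 0.026) were lower and none of the other members was called (33 tested, 0 higher and 2 lower adjusted over the list alone). The list as a whole had a median of 0.66 in the opposite direction (camera adjusted p = 0.038; adjusted p = 0.799 with an estimated correlation). Its median was 1.34 in ISO replicate 3, 0.53 in ISO replicate 1 and −0.31 in ISO replicate 2. Endoplasmic reticulum stress genes had 1 of 23 members lower (1 higher and 4 lower adjusted over the list alone), the chaperone gene Hspa5 at −0.89 (SE 0.15, edgeR adjusted p = 0.026), with a median of −0.12 (camera adjusted p = 0.0331; adjusted p = 0.703 with an estimated correlation).

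Antioxidant and metal-response genes had 1 of 22 members higher (4 higher and 3 lower adjusted over the list alone), the metallothionein gene Mt2A at 1.79 (SE 0.33, edgeR adjusted p = 0.0327), with a median of −0.13, a mean of 0.14 and a camera adjusted p of 0.474. Cell death and muscle atrophy genes had 2 of 26 members higher (2 higher and 0 lower adjusted over the list alone), the autophagy receptor gene Sqstm1 at 0.63 (SE 0.12, edgeR adjusted p = 0.0385) and the pore-forming protein gene Gsdmd at 0.77 (SE 0.17, edgeR adjusted p = 0.0494), with a median of 0.18 (camera adjusted p = 0.176). In the list of renin-angiotensin, endothelin and natriuretic receptor genes, the angiotensin-converting enzyme gene Ace was higher at 1.12 (SE 0.20, edgeR adjusted p = 0.0305) and no other of 16 members was called (1 higher and 1 lower adjusted over the list alone; median 0.00, camera adjusted p = 0.976).

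Markers of other cell types gave no edgeR calls in most lists. Endothelial markers had a median of −0.04 over 16 members (camera adjusted p = 0.713), with the water channel gene Aqp1 at 0.20 (SE 0.17). Smooth muscle and pericyte markers had a median of −0.06 over 16 members (camera adjusted p = 0.899), mesothelial markers −0.06 over 8 (0.899) and lymphocyte markers −0.10 over 10 (0.699). The medians of these 4 lists were above 0 without scaling. The mean of the smooth muscle and pericyte list was 0.05 and that of the mast cell list 0.11, opposite in sign to their medians, and camera gave the mesothelial list the direction opposite to its median. Mast cell markers had a median of −0.12 over 9 members (camera adjusted p = 0.769), neutrophil markers 0.66 over 3 (0.619) and skeletal muscle markers 0.11 over 5 (0.745). Lung and thymocyte markers had 1 tested member each and no list test, with Ager at 0.28 (SE 0.31) and Cd1d1 at −0.22 (SE 0.17). None of these 9 lists had an edgeR call. An unadjusted edgeR p under 0.05 was reached by 1 endothelial, 4 smooth muscle, 2 lymphocyte, 2 neutrophil and 1 skeletal muscle marker and by 0 of the others. DESeq2 called 1 endothelial, 2 smooth muscle, 1 lymphocyte and 1 skeletal muscle marker, and voom called 1 skeletal muscle marker.

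A further 3 marker lists passed camera. Red blood cell markers had a median of −0.85 over 9 members with none called (camera adjusted p = 7.84e-04; adjusted p = 0.351 with an estimated correlation), and −1.79 in ISO replicate 3. Adipocyte markers had a median of 0.60 over 6 members with none called (camera adjusted p = 0.00887; adjusted p = 0.255 with an estimated correlation; fry adjusted p = 0.00321). The filter left out Adipoq, Plin1, Cidec, Lep, Retn and Ucp1, named after their counts were seen, so the median does not cover them. Adipoq had 0, 14 and 0 counts in saline and 30, 0 and 0 in ISO replicates 1 to 3, and Plin1 0, 10 and 0 against 10, 1 and 0. In the red blood cell and adipocyte lists 3 members each had an unadjusted edgeR p under 0.05, while DESeq2 called 2 and 1 and voom 0. Schwann cell and neuron markers had a median of 0.36 over 10 members (camera adjusted p = 0.0141; adjusted p = 0.486 with an estimated correlation), and 1 was called, the noradrenaline synthesis gene Dbh at 2.07 (SE 0.32, edgeR adjusted p = 0.0195).

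Lists that follow sample handling and RNA were tested in the same way. Ribosomal protein genes had a median of 0.36 over 30 members (camera adjusted p = 1.05e-08; adjusted p = 0.564 with an estimated correlation), and 1 was called, Rpl3 at 1.06 (SE 0.22, edgeR adjusted p = 0.045). Immediate early genes, which respond to handling within minutes, had a median of 0.31 over 22 members with none called by edgeR (camera adjusted p = 0.0128; adjusted p = 0.564 with an estimated correlation), and 0.65 in ISO replicate 3. Circadian clock genes had a median of −0.16 and a mean of 0.05 over 17 members (camera adjusted p = 0.691), and mitochondrially encoded genes a median of −0.26 over 13 (0.452), with no edgeR call in either. An unadjusted edgeR p under 0.05 was reached by 6 immediate early, 6 clock and 0 mitochondrial genes, and DESeq2 called 4, 4 and 0 of them and voom 0.

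**Figure D3:**
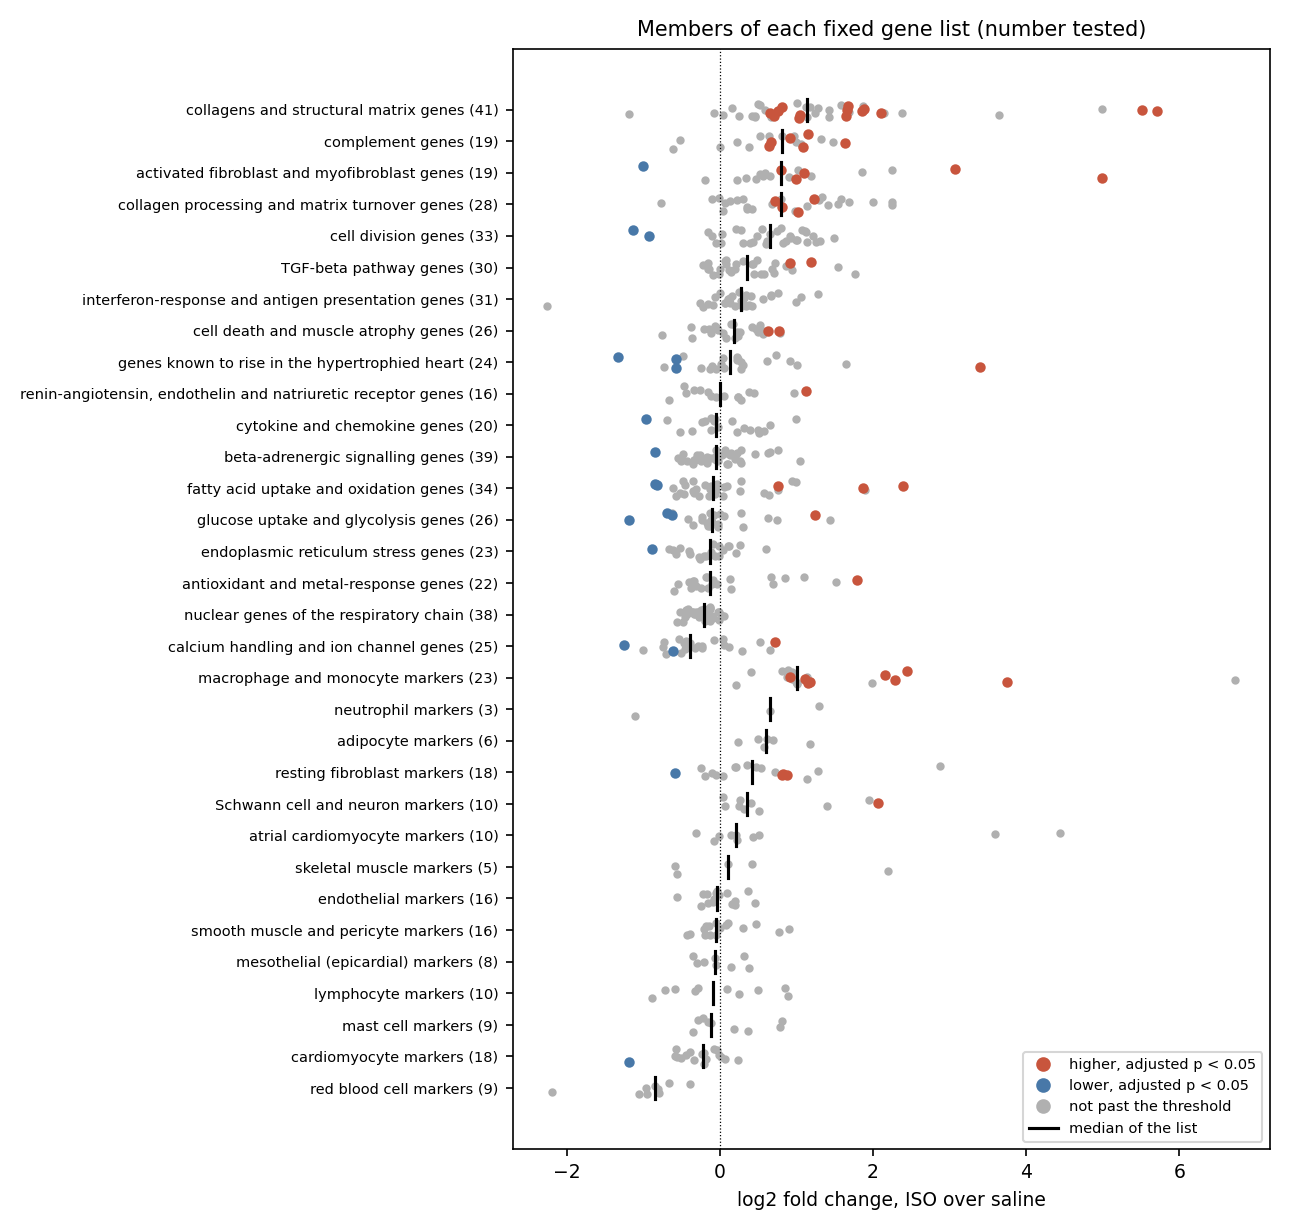
Log2 fold changes, ISO over saline, of the tested members of each pathway and cell type list, with 1 point per gene and a bar at the median of the list. Collagens and structural matrix genes (median 1.14) and macrophage and monocyte markers (median 1.01) lie farthest to the right, and red blood cell markers (median −0.85) farthest to the left.

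With the preset correlation, 17 of 36 tested lists passed camera, and none did with an estimated correlation. Regroupings of the libraries that mix ISO and saline passed 7 to 20 lists with the preset correlation. Their sides hold unequal numbers of ISO libraries, so an effect of ISO can carry into them. These counts therefore give no rate of false passes. As none passed with an estimated correlation, a pass with the preset one does not by itself show an effect of ISO. By fry, 2 lists passed, the resting fibroblast and adipocyte markers, the latter with 6 of 12 members tested.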

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

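All tests of explanations in this part were chosen after the result was seen, except the other splits of the libraries. Rows without a gene name were left out of the comparison and hold signal of their own. Of 661 such rows tested together with the named genes, 6 were higher and 14 were lower in ISO than in saline by edgeR at an adjusted p under 0.05.

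The medians of the matrix and macrophage lists lay above 0, at 1.14 (bootstrap bounds over members 0.763 to 1.58) and 1.01 (0.947 to 1.17), although neither list passed camera with an estimated correlation or fry. The bounds here resample the genes of a list, not the rats, so they hold no spread between rats. Relative to saline, the matrix median was 1.08, 0.518 and 1.8 in ISO replicates 1 to 3. The macrophage median was 0.934, 0.718 and 1.61 in them, and the endothelial median 0.047, 0.0439 and −0.132. A lower share of cardiomyocytes would raise the markers of every other cell type alike. Over all libraries the endothelial median was −0.0438, with an upper bound of 0.155 under both lower bounds. The smooth muscle and pericyte median was −0.0555 (−0.189 to 0.155). The 6 tested adipocyte markers at 0.597 (0.368 to 0.935) and Schwann cell and neuron markers at 0.357 (0.164 to 1.4) lay above 0. The adipocyte median does not cover Adipoq, Plin1 and the other members that the filter left out. Cardiomyocyte markers lay below it at −0.221 (−0.471 to −0.0833). The lists thus did not move alike, which argues against a lower share as the only cause, while a part for it stays open. ISO replicate 3 alone does not carry the matrix pattern, since the median without it was 0.798. More fibroblasts with no change per cell stays open as an explanation of the matrix pattern. The resting fibroblast median was 0.415, below the matrix bounds, but its own bounds of 0.0372 to 0.812 overlap them. Under the first condition this overlap had counted towards that explanation. A stricter condition, set after the values were seen, left it open. A response to ISO also stays open, as does a change in macrophage number.

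Nppa was higher in ISO, at 5.85, 7.21 and 4.74 times the highest saline library in ISO replicates 1 to 3 by unscaled CPM. Atrial tissue in ISO replicates 2 and 3 is argued against, since the atrial genes Myl4 and Myl7 reached at most 1.55 times their highest saline library there. In ISO replicate 1 both lay at least 31 times above it, and Sln, Bmp10 and Mybphl had 670, 192 and 157 counts against at most 13, 1 and 1 in saline. Atrial tissue may therefore have added to Nppa in that library, and its part there cannot be told apart from a response to ISO. The log2 fold change was 3.42 (SE 0.63) without that library and 3.40 (SE 0.56) with it, so the difference between groups does not rest on it. The call was lost without it (edgeR adjusted p = 0.0749) with no smaller fold, as the unadjusted p rose from 0.000277 to 0.000744 and only 9 genes were called higher and 14 lower in that fit. The genes named here apart from Nppa were chosen after their values were seen.

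LOC103690108, chosen after its values were seen, had 524, 456 and 622 counts in saline and 3, 3 and 0 in ISO. A variant carried by some of these outbred rats, or reads shared with near-identical copies, could switch a gene in this way without regard to treatment. A switched gene was taken as one that stayed under 0.5 CPM in some libraries, lay at least 3 higher in log2(CPM + 0.1) in all others and reached 5 CPM in at least 1. Of 12 such genes, 5 followed a split of 3 against 3 libraries that cuts across the groups, on 4 of the 9 other splits, and 1, LOC103690108 itself, followed the groups. With at least 5 CPM in every library that expressed the gene, 5 genes remained, of which 2 followed such a split and 1 the groups. The bounds of both searches were set after the data were seen, and a looser first look had found more such genes. The prediction, written after the gene was seen, asked for several genes on each split, which was not met. Its condition was made stricter after the values were seen. Under the first condition the values had counted towards a variant or shared reads. A variant, shared reads and an effect of ISO therefore cannot be told apart with 3 rats per group.

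The 6 libraries form only 10 splits of 3 against 3, too few for a share under 0.05. The real split called 409 genes and the highest other split 1. For matrix genes the counts were 14 and 0, and for the hypertrophy list 4 and 0, with 1 split as large in each case, the real one. The other splits mix the groups, so a difference between ISO and saline becomes spread within their sides. Low counts of genes there were thus likely in advance and add no support for an effect. For lists past camera with the preset correlation, the real split gave 17 and the highest other 20, and 3 splits gave as many as the real one. The other 2 placed ISO replicate 2 with saline replicates 1 and 2 or 1 and 3. Every split that mixes the groups passed lists, from 7 to 20 of them. Such splits hold unequal numbers of ISO libraries on their sides, so an effect of ISO can carry into them. ISO replicate 2 also lay nearest saline on the first principal component, at 7.56. These counts therefore give no rate of false passes, and their cause was not tested. No list passed with an estimated correlation, so a pass with the preset one does not by itself show an effect of ISO.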

How the results depend on the processing

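Keeping the rows without a gene name was chosen after the data were seen. The main counts were 203 genes higher and 206 lower, 4 called members of the hypertrophy list, 14 of the matrix list and 17 lists. DESeq2's size factors, the filter of 1 CPM in 3 libraries, voom, mitochondrial genes left out and rows without a name kept gave counts of genes and members within 1.5 times of these. The count of lists was computed anew only with an estimated correlation, fry, the replicate block and each library left out. No scaling gave 123 lower. No filter gave 322 higher and 22 matrix members, with 20094 genes tested. DESeq2 gave 752 higher, 653 lower, 8 hypertrophy and 24 matrix members. The series' rule, which uses no adjustment, gave 1214 higher, 623 lower, 9 and 29 members in DESeq2 and 1193 higher, 619 lower, 8 and 31 members in edgeR. An adjusted p under 0.01 left 4 higher, 7 lower and 0 members of either list by edgeR, against 3149 genes at an unadjusted p under 0.05. Apart from these stricter or looser thresholds, the cause was not tested.

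With each library left out in turn, the counts ran from 6 to 492 higher, 5 to 346 lower, 0 to 8 hypertrophy members, 0 to 30 matrix members and 13 to 18 lists; these fits had 5 libraries, and the highest counts all came without ISO replicate 2. With an estimated correlation 0 lists passed and with fry 2, and the cause was not tested. The first component held 41% over the 500 most variable genes. Of 59 called named genes, DESeq2 kept 59, voom 50 and an adjusted p under 0.01 kept 2, and none reversed under any alternative.

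The replicate numbers did not pair the libraries: same-numbered libraries correlated at 0.087, −0.099 and 0.018 in their deviations, and not every library correlated best with its own number. With the replicate block, 15 genes were higher and 13 lower, with 1 hypertrophy and 0 matrix members and 18 lists. In the simulation edgeR recovered 10% of genes changed 1.5-fold, so small changes are mostly missed at this size and depth.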

Other observations

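The tests of the 3 hypotheses here were written before their results were seen, but 2 conditions were set after the p-values were seen: a margin up to p = 0.1 within which a missed threshold was left open, and the demand that a pass also hold with an estimated correlation.

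Pdk4 and Angptl4, which are targets of the PPAR nuclear receptors, were higher in ISO. The hypothesis that PPAR targets rise together was tested on 11 other targets. Of these, 5 lay above 0 and none was called by edgeR, with a median of −0.04 and a camera p of 0.903 (0.956 with an estimated correlation), which argues against a joint rise.

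Pdk4 and Angptl4 also respond to glucocorticoids. Of 10 other glucocorticoid targets, 8 lay above 0, among them Tsc22d3 at 0.69 (edgeR adjusted p = 0.0284), Fkbp5 at 1.09 (0.0887) and Ddit4 at 1.09 (0.105), with a median of 0.57. The camera p was 0.000849 with the preset correlation but 0.139 with an estimated one, so a joint rise of glucocorticoid targets may be present but stays open. As written beforehand, with the preset correlation alone, the prediction was met.

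Myocd, the gene of the cofactor myocardin, Actc1 and Rcan1 were lower in ISO, and a joint fall of targets of myocardin and its partner SRF was tested on 17 other targets. Fhl2 at −1.06 (edgeR adjusted p = 0.0207) and Srf itself at −0.81 (0.026) were lower, while 7 of the 17 lay above 0 and the median was −0.06. The camera p of 0.0502 sat at the threshold of 0.05 and was 0.255 with an estimated correlation, so a joint fall may or may not be present. As written beforehand, a p of 0.05 or more counted against it. Over the 3 hypotheses, the Benjamini-Hochberg adjusted p with the preset correlation were 0.903, 0.00255 and 0.0754. The members named here were chosen after their values were seen.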
